A study of Danio rerio with 6 samples.

How the data were processed

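RNA of whole zebrafish larvae at 108 hours post fertilization (hpf) was measured on 6 single-colour Agilent expression arrays, 3 for wildtype larvae and 3 for larvae homozygous for the clbn (caliban, s841) mutation. Per the labels' protocols, each array measured a separate pool of about 20 individually genotyped larvae, raised at 28.5 °C on a 12-hour light cycle. Phenylthiourea at 0.003%, which blocks pigmentation, was present from 24 hpf. Per the labels' protocols, 1 µg of total RNA was linearly amplified, and 5 µg of the amplified RNA was labelled with Cy3.

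The deposited scanner files hold spot intensity values made with Agilent Feature Extraction 9.5.3.1, per the file headers. Per the file headers, the processed intensity of each spot was background-subtracted and detrended within its array, with no scaling between arrays. The scanner software's marks for spots well above background, saturated or outlying came with them. The deposited series table holds linear ratios of each array to a reference level per probe that no header states, with column medians from 0.953 to 1.05. Per the submitters' processing notes, Agilent Feature Extraction and limma were used, with no further settings recorded. Each column of the series table matched the scanner file of another replicate number of the same genotype (r = 1 across 20310 probes, which are not independent replicates), so replicate numbers here follow the scanner files. The genotype was the same in each match, and no column lacked a listed sample (0 columns).

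Values were computed from the processed intensity. Control spots and spots marked as outlying were left out (2 to 22 outlying spots per array), spots of 1 probe were averaged, and log2 values were expressed relative to the 75th percentile of each array. Of 43603 probes, 43572 had a value on all 6 arrays, and 31781 were well above background on all 3 arrays of at least 1 genotype and were tested. Median signals ran from 82.7 to 112 and 72.6% to 76.2% of probes per array were well above background. The number of arrays limits the precision of each value. Gene names came from the array annotation, updated through a table of current zebrafish genes (assembly GRCz12tu, used for names alone), in which 20869 probes matched. Positions are those of the array annotation (Zv7).

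Clbn mutant and wildtype arrays were compared with limma 3.58.1 in R 4.3.3 (a two-sided moderated test per probe, Benjamini-Hochberg adjusted p under 0.05). A probe is said to have risen, fallen or changed where it passed this test. For a few genes an exact two-sided permutation test was run as well. With 20 assignments of 6 arrays it cannot give a p under 0.1. For gene lists, 1 probe per gene was taken, the one with the highest mean over the 6 arrays. Each list was tested with camera (preset correlation 0.01) against all other tested genes, then with an estimated correlation and with fry. The 26 lists covered the minor and major spliceosome, splicing regulators, RNA decay and export, cell cycle, ribosome biogenesis, stress and sterol pathways, xenobiotic response, the circadian clock, tissue and cell type markers, and known hosts of U12-type introns. Their members, the tests and the settings to be varied were fixed before the data were examined, except where said otherwise.

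Genes were named by a rule fixed at the same time. It took rnpc3, the 10 largest rises and 10 largest falls among genes above background on all arrays with groups that did not overlap, and up to 5 genes per direction that were above background in 1 genotype alone. It also took up to 3 members of each list by smallest adjusted p (2 where fewer than 2 passed) and the measured members of the minor spliceosome list, and a few genes by name. The results of 1 list and of the genes named with it are not reported here. The rule named 80 genes, of which 15 rose, 22 fell and 43 did not pass.

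Arrays of 1 replicate number resembled each other across genotypes. After each genotype's mean was taken out, values across probes correlated by 0.646, 0.486 and 0.725 between arrays of the same number. Correlations for other numbers were at most -0.125, but taking out the means forces negative values there where same-number ones are positive. Because of the same-number resemblance, replicate number was also entered as a block. Replicates 1 and 2 of both genotypes shared a slide (4 arrays), replicate 3 of both lay on another (2 arrays), and slide was entered as a block and split as well. The other alternatives were quantile and median scaling, normexp background correction (offset 50), the deposited ratios, other filters on dim probes, an intensity trend, the mean of all probes of a gene, and leaving out each array. A test of whether probes of 1 gene moved apart, each probe against the mean of the gene's other probes on each array, was added after the data were seen.

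The procedure was tested on simulated data made from the means and spreads of the 31781 probes. Of 200 probes changed by a known amount, 63.0% of those changed 2-fold and 86.0% of those changed 4-fold were recovered, and 3.87% of calls were false. With nothing changed there were 0 calls. A raised list of 25 genes was called and 0 of 25 others were. These lists were random and the simulated probes varied independently. The real arrays resemble each other by replicate number, and estimated correlations within lists reached 0.497 (exocrine pancreas). The simulation therefore does not measure false calls under such resemblance and correlation. Of 100 genes with 1 probe raised 4-fold, 93.0% were found. A reference genome was not used here, so introns were not classed by their sequence. Splicing and sequence variants were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.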

Results

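Transcript levels of whole larvae at 108 hpf were compared between 3 pools of clbn mutants and 3 pools of wildtype larvae. The clbn line carries a mutation in rnpc3, which encodes a protein of the minor (U12-type) spliceosome, the machinery that removes a rare class of introns. The comparison asks which transcripts differ when that machinery is impaired. Between 72.6% and 76.2% of the probes on each array were well above background, and 31781 probes for 25258 gene symbols were tested.

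Rnpc3 itself was 4.16-fold lower in the mutant at the brighter of its 2 probes (chromosome 24, 26759380 to 26759583, Zv7). The log2 level was 0.04 ± 0.34 (SD, n = 3) in wildtype and -2.01 ± 0.30 (SD, n = 3) in the mutant, a log2 change of -2.06 ± 0.22 (SE, adjusted p = 0.0250). The other probe (chromosome 24, 26774382 to 26777030) fell 3.44-fold (log2 -1.78 ± 0.14, SE, adjusted p = 0.0112). On slide 1 the brighter probe differed by -1.94, and on slide 2, with 1 array per genotype, by -2.29. All 3 mutant arrays lay below all 3 wildtype arrays at both probes (exact permutation p = 0.1, the smallest that 6 arrays allow). The line is known to carry a point mutation, which need not lower the level, so this level does not check the genotype labels. The sequences that the probes read were not examined, so altered probe binding was not tested. Leaving out any 1 of the 6 arrays moved the adjusted p of rnpc3 to between 0.0536 and 0.102, with log2 changes from -2.19 to -1.86.

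Of the 10 measured members of the minor spliceosome list, cenatac rose, rnpc3 fell and 8 did not pass. Cenatac, a component of the minor spliceosome, was 3.21-fold higher (chromosome 5, 52527788 to 52527847; log2 1.68 ± 0.18, SE, n = 3 per genotype, adjusted p = 0.0238). The members that did not pass had log2 changes of 0.36 (snrnp48), 0.20 (armc7), 0.00 (pdcd7), -0.08 (scnm1), -0.12 (snrnp25), -0.12 (zcrb1), -0.23 (zmat5) and -0.38 (rbm48). Adjusted over the list alone 2 rose and 2 fell. The list did not shift against other genes (median -0.10, camera adjusted p = 0.668).

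In all, 353 probes differed between the genotypes (171 higher and 182 lower in the mutant), and 214 of them changed at least 2-fold. In each of the 353 the 3 mutant arrays lay to 1 side of the 3 wildtype arrays. Such separation held for 21.0% of all tested probes, where chance gives 10% if the 6 arrays are exchangeable, which arrays that resemble each other by replicate number are not. In the other splits that part each pair of equal number it held for 2.29% to 3.33%. Those splits mix the genotypes, so genotype differences widen their groups and lower this share. It is therefore no chance level to set against the 21.0%. The median log2 change over all tested probes was 0.0004. Of the probes that rose, 60.2% had no gene name other than a provisional one, against 34.1% of those that fell and 44.0% of those that did not pass. Their median log2 level was -4.26 in wildtype and -2.62 in the mutant, against -0.02 and -1.43 for probes that fell and -1.52 and -1.50 for those that did not pass. Of the probes that rose, 17 were not above background on any wildtype array, and 3 that fell were not above background on any mutant array. With replicate number as a block, 1346 probes changed (743 higher, 603 lower, 370 at least 2-fold), 352 of them among the 353. With slide as a block 586 changed (317 higher, 269 lower). On slide 1 alone, with 2 arrays per genotype, limma called 0 probes and 3684 had an unadjusted p under 0.05. Slide 2 held 1 array per genotype and gave no test. With an intensity trend the count was 598, with no filter on dim probes 86, and with normexp background correction 0 (451 at an unadjusted p under 0.05). Without 1 array it was 28, 27 and 25 (without wildtype replicate 1, 2 or 3) and 50, 161 and 19 (without mutant replicate 1, 2 or 3).

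Among named genes above background on all arrays, and by the brightest probe of each gene, the largest rise was that of ppp2r2aa, which encodes a regulatory subunit of a protein phosphatase. It was 8.02-fold higher (chromosome 8, 53702762 to 53703676; log2 3.00 ± 0.29, SE, n = 3 per genotype, adjusted p = 0.0198). Arf4b, a small GTPase of Golgi traffic, was 5.20-fold higher (chromosome 11, 44573521 to 44573580; log2 2.38 ± 0.18, SE, adjusted p = 0.0112). Abi1a, an Abl interactor that acts on the actin cytoskeleton, was 3.54-fold higher at its brightest probe, while its other probes differed by 1.26 and -0.38 on the log2 scale. The next rises after cenatac were those of ugt5a1 (2.66-fold, a glucuronosyltransferase), ccdc191 (2.31-fold), mysm1 (2.28-fold, a histone deubiquitinase), tspan5b (2.17-fold, other probe 0.15 on the log2 scale), cuedc1b (2.13-fold, other probe -0.53) and slx4ip (1.86-fold, other probe 1.33). In wildtype the other probe of cuedc1b was the brighter one. Mapk13, a stress-activated kinase, was above background in the mutant alone and at least 3.91-fold higher. Rangap1b, the activator of the nuclear transport GTPase Ran, was at least 1.71-fold higher by the same rule. Mysm1 (adjusted p = 0.0641) and slx4ip (0.0684) no longer passed with the deposited ratios, rangap1b with an intensity trend (0.0601), or tspan5b (0.106) and cuedc1b (0.395) as the mean of their probes. Normexp background correction without spots of high local background lowered the log2 changes to 0.37 for mapk13 (adjusted p = 0.239) and 0.11 for rangap1b (0.858), below the bounds given above, and to 0.46 for ugt5a1 (0.0886) and 0.44 for mysm1 (0.0832), and ended these 4 calls.

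The largest falls among named genes included lens proteins. Grifin, a galectin-related lens protein, was 6.32-fold lower (chromosome 3, 39595503 to 39595562; log2 -2.66 ± 0.34, SE, n = 3 per genotype, adjusted p = 0.0347). Crygmxl1, a gamma crystallin, was 4.71-fold lower and cryaa, which encodes alpha A crystallin, 4.45-fold lower. The astacin protease gene c6ast3 was 5.19-fold lower, actl6b, a subunit of the neuronal chromatin remodelling complex, 4.90-fold, mocs3, of molybdenum cofactor synthesis, 4.62-fold, and the organic anion transporter gene slco5a1a 4.56-fold. Endou2 was 3.90-fold lower and cyp3a65, a drug-metabolizing enzyme of liver and intestine, 3.69-fold (log2 -1.88 ± 0.17, SE, adjusted p = 0.0170). Rec8b, a meiotic cohesin, and plp2a were above background in wildtype alone and at least 1.82-fold and 1.65-fold lower. Cryaa no longer passed with slide as a block (adjusted p = 0.0547), quantile scaling (0.0527) or the deposited ratios (0.0523). Rec8b no longer passed with slide as a block (adjusted p = 0.0558), quantile (0.0582) or median scaling (0.0513), an intensity trend (0.0549) or the mean of a gene's probes (0.0511). The normexp correction without spots of high local background brought rec8b to -0.17 (adjusted p = 0.598) and plp2a to -0.27 (0.421), changes smaller than their bounds, and slco5a1a to -0.86 (0.0501), and ended these calls. With no filter on dim probes 29 of the 37 named genes that passed, rnpc3, cenatac, grifin and cryaa among them, no longer did. On slide 1 alone, with fewer arrays, none of the 80 genes named by the rule passed (0 probes). For each of the 37 named genes that passed, leaving out 1 array ended the call for between 2 and 6 of the 6 arrays.

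**Figure D1:**
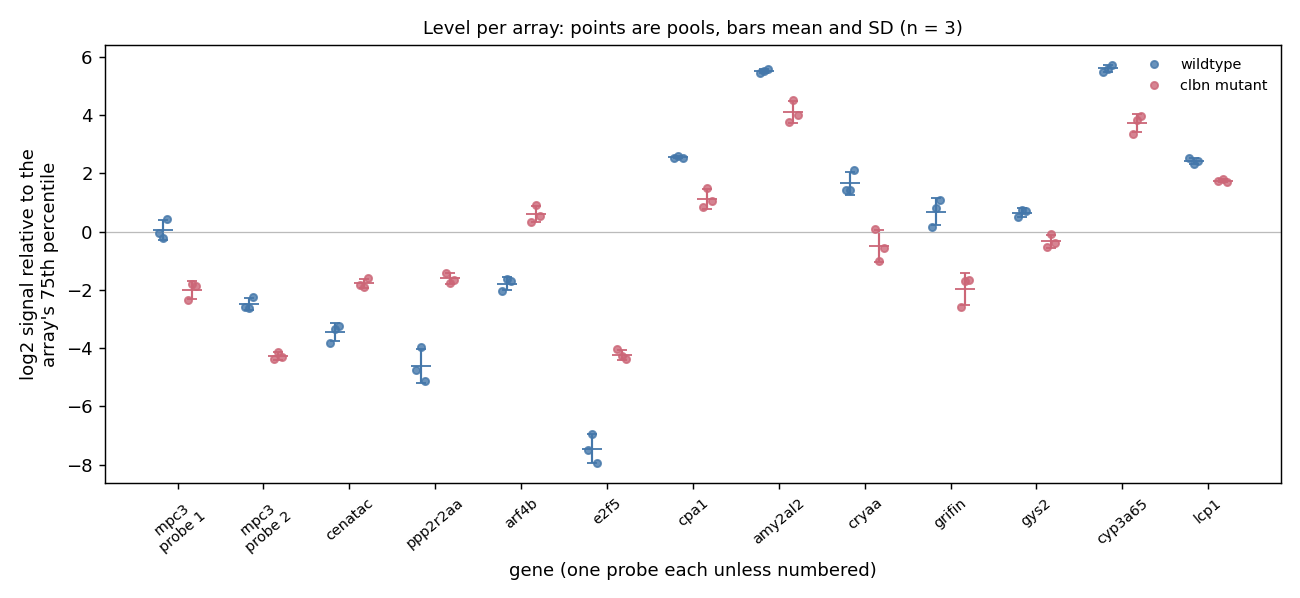
Log2 signal of 13 probes relative to the 75th percentile of each array, with 1 point per pool, and bars for the mean and SD (n = 3). Rnpc3 was lower at both probes, cenatac, ppp2r2aa, arf4b and e2f5 were higher, and the pancreas, lens, liver, intestine and leukocyte genes to the right were lower.

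Digestive organ and lens transcripts were lower in the mutant. The exocrine pancreas list, which holds digestive enzymes, had a median log2 change of -1.23 over 21 members (camera adjusted p = 4.79e-16, 0.383 with an estimated correlation). Of these, cpa1 (carboxypeptidase, -1.42 ± 0.18, SE) and amy2al2 (amylase, -1.42 ± 0.19) fell, and 19 did not pass. Adjusted over the list alone 19 members fell, and with replicate number as a block 10 fell over all probes. The hepatocyte list had a median of -0.31 over 50 members (camera adjusted p = 7.13e-11, 0.383 with an estimated correlation). In it serpinf2a, an inhibitor of plasmin (-0.92), and gys2, liver glycogen synthase (-0.98), fell, and 48 did not pass. With slide as a block neither passed (adjusted p = 0.0504 and 0.0524), and with replicate number as a block 8 members fell over all probes. Adjusted over the list alone 18 fell and 1 rose. The 1 that rose was hamp, the gene of the iron hormone hepcidin, at 2.98, which did not pass over all probes (adjusted p = 0.0620). The enterocyte list had a median of -0.23 over 32 members (camera adjusted p = 9.59e-05, 0.442 with an estimated correlation). The fatty acid elongase gene elovl2 fell (-1.23), 31 members did not pass, and adjusted over the list alone 9 fell and 1 rose. With replicate number as a block 6 fell and 1 rose over all probes. Among lens crystallins the median was -0.74 over 26 members (camera adjusted p = 9.91e-12, 0.383 with an estimated correlation). Crygm2f (-1.65) and cryaa (-2.15) fell, and 24 did not pass. Adjusted over the list alone 16 fell, and with replicate number as a block 2 fell over all probes. The medians of the pancreas, hepatocyte, enterocyte and lens lists were -1.12, -0.34, -0.23 and -0.54 on slide 1 and -1.11, -0.31, -0.32 and -1.07 on slide 2.

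The leukocyte list was lower by a smaller amount (median -0.13, mean -0.04 over 31 members, camera adjusted p = 0.00841, 0.383 with an estimated correlation). Coro1a (-0.61) and lcp1 (-0.68), which encode actin-binding proteins of leukocytes, fell, 29 members did not pass, and 4 fell and 1 rose adjusted over the list alone, again hamp, which both lists hold. Leaving out 1 array moved the median of the list to between -0.21 and -0.11. Coro1a no longer passed with the deposited ratios (adjusted p = 0.0502), and lcp1 under median scaling (0.0513). Under normexp background correction the call of the leukocyte list was lost (adjusted p = 0.154), as was that of the enterocyte list (0.114). Fast skeletal muscle genes had a median of -0.07 over 27 members, none of which passed on either adjustment (0 members, camera adjusted p = 0.0211, 0.523 with an estimated correlation). That call was lost under quantile scaling (median 0.0002, adjusted p = 0.582) and turned under normexp background correction (median 0.11), and leaving out 1 array moved the median to between -0.11 and -0.04. It was also lost without wildtype replicate 1 (adjusted p = 0.189), wildtype replicate 2 (0.0538), mutant replicate 2 (0.0526) or mutant replicate 3 (0.0901). In the list of glia and myelin, plp1b, a myelin proteolipid gene, fell (-0.95 ± 0.11, SE, adjusted p = 0.0305), 13 members did not pass and 4 fell adjusted over the list alone. The list as a whole did not pass camera (median -0.06, adjusted p = 0.0628), while fry, which tests whether a list's genes move on balance in 1 direction, gave adjusted p = 0.00761. It passed camera without wildtype replicate 2 (adjusted p = 0.0365), with the deposited ratios (0.0326) and with no filter on dim probes (0.0243).

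The cell cycle, ribosome biogenesis, major spliceosome and splicing regulator lists were called higher, by small amounts, by camera with the preset correlation. Neither camera with an estimated correlation nor fry called them. Cell cycle and DNA replication genes had a median of 0.31 over 45 members (camera adjusted p = 2.40e-10, 0.442 with an estimated correlation). Rpa3, a subunit of the replication protein that binds single-stranded DNA, rose (0.60 ± 0.09, SE, adjusted p = 0.0453), 44 members did not pass, and 13 rose adjusted over the list alone. With replicate number as a block 10 members of the list rose and 1 fell. Rpa3 no longer passed under median scaling (adjusted p = 0.0548), with the deposited ratios (0.115) or as the mean of its probes (0.0595). Ribosome biogenesis genes had a median of 0.14 over 50 members (camera adjusted p = 1.73e-06, 0.442 with an estimated correlation) and major spliceosome genes 0.10 over 82 members (1.55e-06, 0.383 with an estimated correlation). No member of either list passed (0 on both adjustments). With replicate number as a block 1 and 3 members rose over all probes, snrpe of the major spliceosome list among them. Snrpe (0.55, adjusted p = 0.0557) and the nucleolar genes npm1a (0.42) and fbl (0.35) had values on that side. Snrpe is also in the list of known U12-type intron hosts. Splicing regulators of the SR and hnRNP families had a median of 0.08 over 53 members with 0 passing on both adjustments (camera adjusted p = 0.0107, 0.523 with an estimated correlation). This call was lost without wildtype replicate 3 (adjusted p = 0.114) or mutant replicate 1 (0.0633), and on slide 1 (0.114), and leaving out 1 array moved the median to between 0.03 and 0.11. The slide 1 and slide 2 medians were 0.29 and 0.37 for the cell cycle, 0.19 and 0.05 for ribosome biogenesis, 0.12 and 0.10 for the major spliceosome, and 0.03 and 0.13 for the splicing regulators.

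Stress and lipid synthesis lists were also called higher by camera with the preset correlation alone. In the unfolded protein response (median 0.10, 35 members, camera adjusted p = 0.00838, 0.523 with an estimated correlation) pdia4, a protein disulfide isomerase of the endoplasmic reticulum, rose (0.62, adjusted p = 0.0498), and 34 did not pass. The other probes of pdia4 were at 0.28 and 1.59, and it is among the genes whose probes moved apart. Its call was lost under quantile (adjusted p = 0.0506) or median scaling (0.0671), with the deposited ratios (0.107) and with no filter on dim probes (0.109). Adjusted over the list alone 6 rose and 1 fell. Heat shock genes had a median of 0.18 over 23 members (camera adjusted p = 0.00382, 0.487 with an estimated correlation), with hspd1, a mitochondrial chaperonin, at 0.78 (adjusted p = 0.0897). Sterol and fatty acid synthesis genes had a median of 0.29 over 27 members (camera adjusted p = 0.00382, 0.546 with an estimated correlation), with mvda at 0.91 (adjusted p = 0.0764) and ebp at 1.28. No member of the heat shock or sterol lists passed over all probes, and 0 and 2 rose adjusted over the list alone. With replicate number as a block 2 and 6 members rose over all probes, hspd1, mvda and ebp among them. The slide 1 and slide 2 medians were 0.09 and 0.14 for the unfolded protein response, 0.15 and 0.19 for heat shock and 0.19 and 0.52 for sterols. Leaving out 1 array moved these medians to between 0.04 and 0.16, 0.08 and 0.26, and 0.10 and 0.52, in that order. Without wildtype replicate 3 the calls of all 3 lists were lost (adjusted p = 0.0805, 0.0716 and 0.0819), as were those of the unfolded protein response (0.0529) and heat shock (0.0544) without mutant replicate 2 and that of sterols without mutant replicate 1 (0.0534) and on slide 1 (0.0760).

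In all, camera called 13 of the 26 lists with the preset correlation (7 higher and 6 lower) and 0 with an estimated correlation, where the smallest adjusted p was 0.383. Fry called 1 list, glia and myelin. In other splits of the 6 arrays into 3 and 3, camera with the preset correlation called between 1 and 10 lists. With replicate number as a block 13 lists were called, with slide as a block 14, the addition being the circadian clock (adjusted p = 0.0489), and on slide 1 alone 11. Over all probes with the replicate block, 2 splicing regulators rose and 1 fast skeletal muscle gene fell. In the unfolded protein response 5 genes rose and 1 fell with it. Among leukocyte genes 4 fell and 1 rose, and among glia and myelin genes 3 fell.

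**Figure D2:**
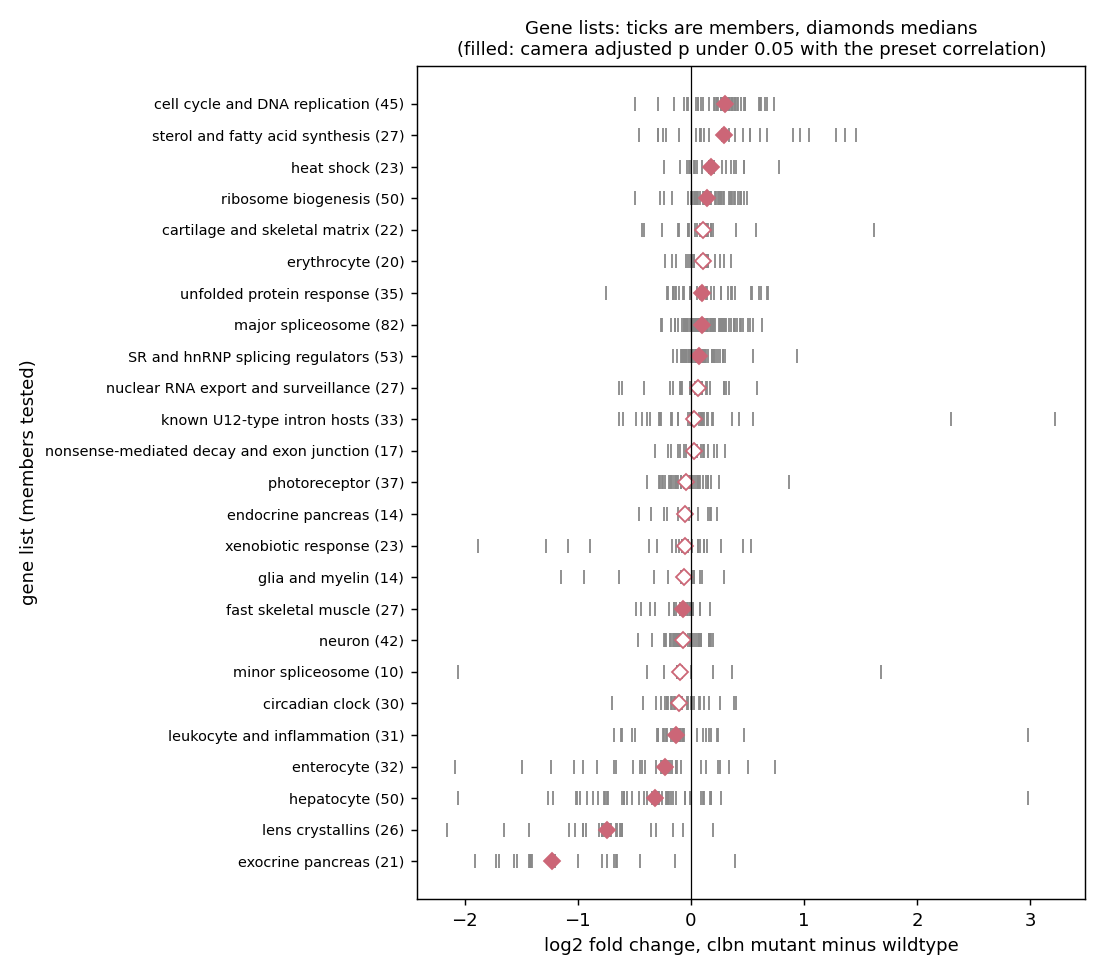
Log2 fold change (mutant minus wildtype) of the tested members of gene lists, with a tick per gene and a diamond for the median of each list, filled where camera called the list with the preset correlation. Exocrine pancreas has the lowest median (-1.23) and cell cycle the highest (0.31). Fast skeletal muscle, whose diamond is filled, turned direction under normexp background correction.

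In nuclear RNA export and surveillance (median 0.06, 27 members, camera adjusted p = 0.291) exosc9, a subunit of the RNA exosome, fell (-0.61 ± 0.08, SE, adjusted p = 0.0369), and thoc6 was at 0.59 (adjusted p = 0.0761). Adjusted over the list alone 2 of its members fell and 1 rose. With replicate number as a block 2 fell and 1, thoc6, rose over all probes. Under normexp background correction without spots of high local background the list was called higher (median 0.07, adjusted p = 0.0351). Xenobiotic response genes did not shift (median -0.05, 23 members, camera adjusted p = 0.291), with cyp3a65 the 1 member that fell on both adjustments. The remaining lists had no camera call and no member that passed (0 on both adjustments). Their medians and camera adjusted p were 0.03 and 0.588 for nonsense-mediated decay, -0.05 and 0.551 for endocrine pancreas, 0.10 and 0.166 for erythrocytes, -0.04 and 0.291 for photoreceptors, -0.07 and 0.188 for neurons, 0.10 and 0.215 for cartilage, and -0.11 and 0.249 for the circadian clock. Leaving out 1 array moved the nonsense-mediated decay median to between -0.03 and 0.08. It moved that of cartilage to between 0.04 and 0.13 and that of the circadian clock to between -0.17 and -0.01. Erythrocyte genes passed without wildtype replicate 1 (median 0.19, adjusted p = 0.00443), and cartilage genes under quantile scaling (median 0.14, adjusted p = 0.0198). With replicate number as a block 1 photoreceptor gene rose over all probes, and of cartilage genes 1 rose and 1 fell.

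Known hosts of U12-type introns did not shift as a group (median 0.03 over 33 members, slide 1 -0.06, slide 2 0.05, camera adjusted p = 0.575). Of these, e2f5 and mapk13 rose and 31 did not pass. Adjusted over the list alone 3 rose, the addition being snrpe, which the major spliceosome list also holds. With replicate number as a block 3 rose over all probes. E2f5, a transcription factor of the cell cycle, was 9.32-fold higher at the probe with the higher mean over the 6 arrays (chromosome 2, 26122176 to 26122235, log2 3.22 ± 0.26, SE, n = 3 per genotype, adjusted p = 0.0122). In wildtype this probe was the dimmer of the gene's 2 probes and was above background on 1 of the 3 arrays. That fold (95% interval 6.05 to 14.3) is a fitted value that rests on wildtype levels near background. It was 7.11-fold with wildtype values set no lower than the lowest value above background on each array. The other e2f5 probe did not pass (0.30, adjusted p = 0.610).

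Probes of some other genes disagreed in this way as well. In 30 of 5193 genes with 2 or more tested probes, 1 probe differed from the mean of the gene's other probes by more in 1 genotype than in the other (adjusted p under 0.05), a test added after the data were seen. The probe that moved had a higher level in the mutant than in wildtype for 24 genes, of which 19 passed on their own, and a lower one for 6, of which 4 did. The 24 differences ran from 1.38-fold to 13.5-fold, with a median of 3.44-fold when the 2 probes not above background on any wildtype array stand at their bound and 4.35-fold as fitted. Those of slc25a14, a mitochondrial carrier (log2 3.75, other probe -0.02), slc9a6a, an endosomal sodium-proton exchanger (2.56, other probe -0.45), and exosc5, of the RNA exosome (2.90, other probes 0.10 and 0.18) rose. The same held for znf143b (6.14-fold), garnl3 (5.27-fold), slc12a4 (5.24-fold), btaf1 (4.92-fold) and the kinase gene braf (3.34-fold, other probes from -0.11 to -0.02 on the log2 scale). The probes of garnl3 and braf were above background on 2 and 1 of the 3 wildtype arrays, and with wildtype values raised as for e2f5 their folds were 5.11 and 3.04. The moved probe of alg6, of protein glycosylation, was above background in the mutant alone and at least 2.46-fold higher. In the opposite direction, 1 probe of snx7, a sorting nexin, fell 15.5-fold (log2 -3.96 ± 0.15, SE, adjusted p = 0.00179) while its other probe rose (0.78, adjusted p = 0.0279). These genes were singled out after their values were seen. The count was 31 with replicate number as a block and 23 with slide as a block. On slide 1 alone it was 5, and without 1 array it was between 7 and 19.

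**Figure D3:**
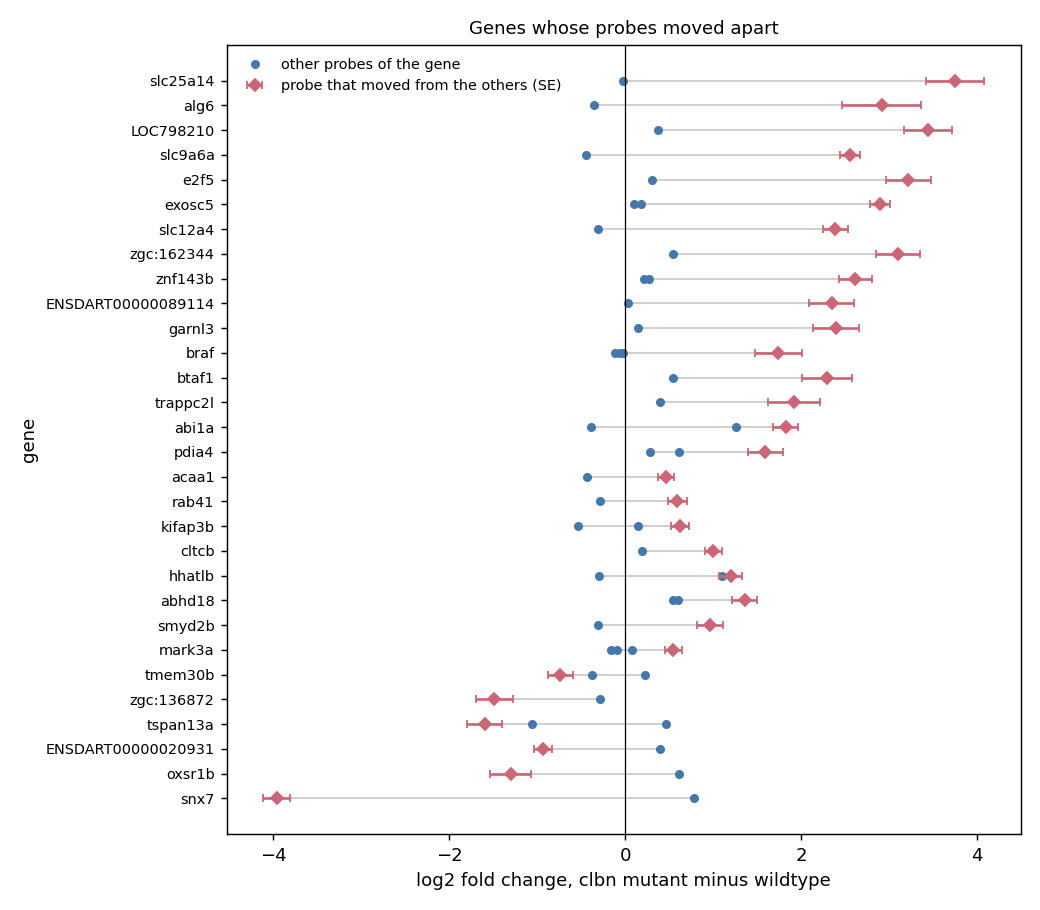
Log2 fold change (mutant minus wildtype) of each probe of the 30 genes whose probes moved apart. A diamond and its SE mark the probe of largest absolute change in each gene, called the probe that moved, and a point marks each other probe. The diamonds of 24 genes lie to the right of the mean of the gene's other probes and those of 6 to the left. The diamonds of alg6 and LOC798210 are fitted values of probes not above background in wildtype, with bounds of at least 2.46-fold and 2.50-fold.

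Changed probes were concentrated on chromosome 24, on which rnpc3 lies. Of 805 tested probes there, 50 changed (6.21%), of which 21 rose and 29 fell. Elsewhere 275 of 28320 probes with a position changed (0.971%). The odds ratio was 6.75 (95% interval 4.85 to 9.24, two-sided Fisher's exact p = 5.18e-23, a test chosen after the data were seen). Probes of 1 gene are not independent. Counted with 1 probe per gene symbol, 36 of 638 symbols on chromosome 24 changed against 218 of 22390 elsewhere (odds ratio 6.08, 95% interval 4.11 to 8.78). The chromosome with the next highest share was chromosome 21, at 1.93%. Of the genes described above, rnpc3, abi1a, ccdc191, elovl2, pdia4 and snx7 lie on chromosome 24.

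**Figure D4:**
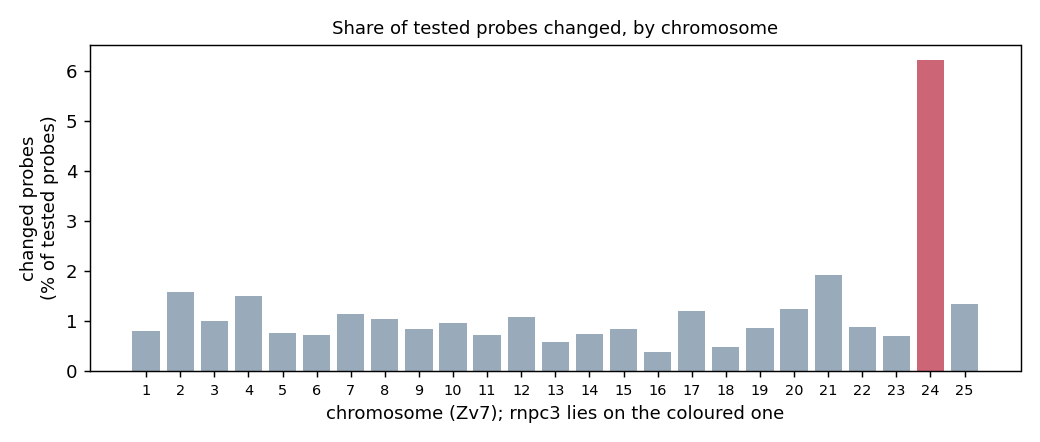
Percent of tested probes that changed, by chromosome (Zv7 positions of the array annotation), with the chromosome of rnpc3 coloured. Chromosome 24 stands at 6.21% and the others are at or below 1.93%.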

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

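The alternatives were fixed before the data were examined, except normexp background correction without spots of high local background and the alternatives for genes whose probes moved apart, a test itself added later, which were chosen after seeing the data. Of the 353 changed probes, 262 kept their sign under normexp as planned, and each one tested did so under the other alternatives that test probes (311 of them were tested where all 6 arrays had to be above background). The count lay between 292 and 428 with quantile or median scaling, the deposited ratios (384, of which 135 higher and 249 lower), probes above background on all 6 arrays, and the added background correction (428, of which 185 higher and 243 lower). Under normexp as planned 0 probes passed (451 at an unadjusted p under 0.05), 0 were higher, 0 lower and 0 changed at least 2-fold, 0 genes had probes that moved apart, and the median of all probes moved by -0.25. Rnpc3 was at -1.43 there (adjusted p = 0.795), ugt5a1 at -0.51, mysm1 at -0.50, cuedc1b at -0.10, slx4ip at -0.23, mapk13 at -0.71, rangap1b at -0.88 and e2f5 at -0.44. The fast skeletal muscle list had a median of 0.11 (adjusted p = 0.00979) and the photoreceptor list, at a median of -0.0455, was called higher (0.0423). The lists of nonsense-mediated decay, RNA export and cartilage were also called higher there, and those of enterocytes and leukocytes lost their calls. The medians of the hepatocyte, major spliceosome, splicing regulator and ribosome biogenesis lists moved there to -0.15, 0.23, 0.21 and 0.22 and their calls were kept. Most of the difference goes with 21 spots with a local background above 200 on wildtype replicates 1 and 3 and mutant replicate 1, where the fitted background was -437, -659 and -477 with them and -8.11, -2.23 and -5.81 without them. Without them 247 of the 353 calls were shared, 7 named genes that had passed (ugt5a1, mysm1, slco5a1a, mapk13, rangap1b, rec8b and plp2a) still did not pass, and the RNA export list was called higher (median 0.07, adjusted p = 0.0351). With no filter on dim probes, which raises the number tested to 43572, 86 probes changed (61 higher, 25 lower, 86 at least 2-fold), 14 genes had probes that moved apart, and rnpc3 stayed at -2.06 (adjusted p = 0.0548). With an intensity trend 598 changed (273 higher, 325 lower). With slide as a block 586 changed (317 higher). With the replicate block 1346 changed (743 higher, 603 lower, 370 at least 2-fold). The cause of these 3 differences was not tested. That block added 13 calls among the 80 named genes, ended none and changed no list's call. On slide 1 alone, with fewer arrays, 0 probes passed, 0 higher, 0 lower and 0 at least 2-fold, 5 genes had probes that moved apart, and rnpc3 was at -1.94 (adjusted p = 0.241). Leaving out 1 array left from 19 to 161 changed probes (16 to 64 higher, 3 to 97 lower, 19 to 152 at least 2-fold) and 7 to 19 genes whose probes moved apart, and rnpc3 was between -2.19 and -1.86 and passed in none. Of the 37 named genes that passed, 30 kept their sign under each alternative. Among values that did not pass in either setting, 20 turned sign. With an estimated correlation, which is read from each list's own members, camera called 0 lists. The alternatives on introns classed by sequence and on genes matched for introns were not run, since a genome was not used here. Probes near background limit the folds of the rises, since 17 of the probes that rose were not above background in wildtype.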

Other observations

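The genes of this paragraph were chosen after their values were seen. Some genes that act in T lymphocytes were lower in the mutant, and no list of such genes was tested. The T cell receptor alpha constant gene trac fell (log2 -1.13 ± 0.16, SE, n = 3 per genotype, adjusted p = 0.0424), as did the receptor-associated kinase gene zap70 (-0.67, adjusted p = 0.0493) and the chemokine receptor gene ccr9b (-1.49, adjusted p = 0.0160). Themis, a regulator of T cell selection, was at -0.93 and did not pass (adjusted p = 0.112). Neither did lck (-0.61, adjusted p = 0.106), ikzf1 (-0.29, 0.256), rag2 (-0.52, 0.324) or rag1 (-0.29, 0.403). The keratin genes krt92 (-0.86, adjusted p = 0.0339) and krt93 (-1.80, adjusted p = 0.0408) fell. Of DNA repair genes, rad52 (0.67, adjusted p = 0.0423) and mre11a (0.62, adjusted p = 0.0436) rose, and rad51b (0.44, adjusted p = 0.254) and mcph1 (1.01, adjusted p = 0.0882) did not pass. Orc5, of the origin recognition complex, was at 0.79 (adjusted p = 0.0752). The values of trac, zap70 and ccr9b were -0.99, -0.63 and -1.47 on slide 1 and -1.42, -0.74 and -1.51 on slide 2. On chromosome 24, xrcc2 (1.41, adjusted p = 0.137) and ezh2 (0.79, adjusted p = 0.116) did not pass.

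Of the tests below, those of other splits for the probe count, of U12-type hosts with and without e2f5, of chromosome 24 as the place of most genes that moved apart, and of distance from rnpc3 were chosen only after the result was seen. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 353 changed probes, 13 shifted lists and 30 genes whose probes moved apart, and 1 of the 10 splits, the real one, gave as many of each. The highest of the other splits gave 0, 10 and 0. Each of these mixes the genotypes, so genotype differences widen its groups and make calls of single probes rarer than by chance alone. The splits that part all pairs of equal replicate number, as the real one does, gave 0 changed probes with and without the replicate block, and 7, 10 and 5 lists. Of 99 unnamed probes that rose and have a position, 38.4% lay within 20 kb of a named probe on the same strand, against 39.2% of unnamed probes that did not pass (odds ratio 0.967, 95% interval 0.627 to 1.48, Fisher's exact p = 0.918).

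In 30 genes the probes moved apart, and in most of them the probe of largest absolute change was higher in the mutant. Noise of dim probes as the cause of them all is argued against by the 24 genes called among probes above background on all 6 arrays. In 27 of 27 genes with known positions the moved probe lay within 200 kb of another on the same strand. This cannot decide on misplaced probes, since positions and gene names both start from the array annotation and the share among other genes was not computed. Sequence differences near the mutation were not the source of most of them, since 7 of 27 genes (25.9%, 95% interval 11.1% to 46.3%) lie on chromosome 24, but that exceeds the 130 of 4837 other genes (2.69%; odds ratio 12.7, 95% interval 4.44 to 31.8, Fisher's exact p = 6.69e-06) and leaves this source open for those 7. Sequence kept from U12-type introns stays open: known hosts made up 2 of the 30 genes (e2f5 and braf) and 12 of the other genes with several probes (odds ratio 30.5, 95% interval 3.18 to 147, Fisher's exact p = 0.00281), but without e2f5, whose probes were seen to differ beforehand, the ratio was 15.3 (95% interval 0.346 to 110, p = 0.0703). The moved probes of e2f5 and braf were below background on some wildtype arrays, and among the 25 genes whose moved probe was above it on all 6 arrays 0 were known hosts. The list of known hosts held 45 names, 36 of them on the array, and was not drawn from a genome. Genes outside it may be hosts as well, so this 0 does not weigh against kept intron sequence. Whether the probes lie in introns was not tested, since a genome was not used here.

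The pancreas, hepatocyte, enterocyte and lens lists were lower in the mutant, and scaling of the arrays is argued against by the highest of their medians under quantile or median scaling, which was -0.222. A single deviating array is argued against by medians that stayed at or below -0.20 without any 1 array, with camera calls at the preset correlation in 24 of 24 cases (4 lists, each of 6 arrays left out). These calls rest on that correlation, since camera with an estimated one called 0 lists, and with the preset one it called up to 10 lists in other splits of the arrays. Fewer cells of each organ in the mutant may account for lists that fall as a whole, but the lowest share of members below 0 was 78.1%, in the enterocyte list, which leaves this open. Lower transcription in the same number of cells and a delay of development in the mutant stay open and were not tested.

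Changed probes were more frequent on chromosome 24, in both directions. Dim probes are argued against by an odds ratio of 6.995 (95% interval 4.93 to 9.74) among probes above background on all 6 arrays, and a change in copy number by a median log2 change of -0.0171 over the chromosome. Calls were fewer within 15 Mb of rnpc3 (32 of 637 probes, 5.02%) than farther off (18 of 168, 10.7%). The odds ratio was 0.441 (95% interval 0.233 to 0.859) by positions of the older Zv7 assembly. A share of calls that drops beyond 15 Mb was therefore not seen. Most tested probes of the chromosome lie within 15 Mb, so this test cannot show whether calls thin out inside that distance. Sequence differences that thin out with distance from rnpc3 thus stay open. Sequence differences along the whole chromosome that travel with the mutation may remain a source of calls, both as true differences in expression and as altered probe binding. They were not tested, and neither was a direct effect of the mutation on these genes.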
